A study of Mus musculus with 2 samples.

How the data were processed

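Single-cell RNA-seq libraries were made from the crypt epithelium of 1 C57Bl6J mouse on day 6 of infection with the intestinal nematode Heligmosomoides polygyrus. Per the labels, live CD45-negative, EpCam-positive and CD44-positive cells were sorted by the surface protein Sca-1, which the gene Ly6a encodes. The Sca-1-positive fraction is called Sca1pos here and is labelled as granuloma by the submitters, and the Sca-1-negative fraction is called Sca1neg and is labelled as non-granuloma. Per the labels' protocols each fraction was encapsulated on the 10x Genomics Chromium controller with the version 2 chemistry for transcript 3' ends and sequenced on an Illumina HiSeq, so each group holds 1 library. The submitters' processing notes name Seurat 2.0 and the mouse build mm10. The aligner and the counting program are not given in the sources used here.

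The values deposited by the authors are on a natural log scale, ln(1 + UMIs per 10000 UMIs of the cell), for 14421 genes in 26423 cells. A unique molecular identifier (UMI) marks 1 captured transcript. Back-transformed values summed to 10000 in every cell, and the smallest step in each cell gave its total, so UMI numbers were recovered. Of 73351620 non-zero values, 100% were whole within 0.01 UMI. Cell names carried the fraction, which placed 6669 cells in Sca1pos and 19754 in Sca1neg. The authors also deposited 20 cluster tables, numbered 0 to 19, and every cell was in 1 of them. Only the cluster membership of cells was taken from these tables. In the table of cluster 13 gene names stood in another order than the values, with 81 of 14402 named rows equal to the full table by name and all 14421 equal by place. In the other 19 tables all named rows were equal.

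Genes appear to have been filtered in each library separately before the libraries were joined. In Sca1pos 481 genes were listed at 0 and the fewest cells of any other gene were 6. In Sca1neg 340 genes were listed at 0 and the fewest cells of any other gene were 9. A gene listed at 0 may therefore have had a few UMIs, and no fold is given for it.

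Levels are CPM, UMI counts scaled to a total of 1000000, from UMIs summed over the cells of a library or of a cluster within it, with exact Poisson 95% intervals. Log2 ratios of Sca1pos over Sca1neg have exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals. All intervals cover counting error only. With 1 library per group no test was made between the groups, no p-value is given and cells were not treated as replicates. Both sorts came from the same mouse, so no difference has a replicate check. Genes detected in at least 5% of the cells of a library were compared, 9480 in all, and were counted where the levels differed by at least 2-fold.

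The choices that follow were made before the data were examined. The named genes are the 12 with the highest and the 12 with the lowest ratio, ribosomal, mitochondrial and unnamed gene models left out, and a few genes named whatever their values, among them Ly6a, Cd44, Epcam and Lgr5. Gja1 was not analysed here, and some items that these rules take are not reported here. For each authors' cluster the 5 genes with the highest ratio over the mean of the other clusters were taken, among genes detected in at least 25% of its cells. The 32 gene lists comprised 16 cell type lists and 16 programme lists. For each, the median log2 ratio, the members over and under 1.5-fold and the 2 highest and 2 lowest members were taken. The median was placed among those of 10000 random lists of the same size matched on expression in 10 bins, as a description of these libraries. Lists with at least 5 compared members were counted. Some genes stand on more than 1 list. Retnlb and Clca1 are on the goblet and the type 2 list, and Ang4 and Itln1 on the Paneth and the type 2 list. A comparison of cells with and without Ly6a UMIs inside clusters was planned only for data in which the libraries could not be told apart and was not run.

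A cluster was called after a cell type only where at least 3 markers were detected in it and its leading genes did not go against the name. Libraries were compared inside the 17 clusters with at least 20 cells of each. For equal cluster weights, a gene's CPM were averaged over these 17 clusters in each library before the ratio was taken. Shares of cells with a UMI were also taken after thinning each cell to 3000 UMIs, which left out 655 Sca1neg cells and 0 Sca1pos cells. Doublets were not removed for the main values. The scrublet caller in scanpy 1.11.5 marked 3 Sca1pos and 1 Sca1neg cells, too few to have worked, so the 2% of cells with most genes in each library were left out in its place as an alternative. Leaving out the 5% with the highest doublet scores, 333 and 988 cells, was added after seeing the data.

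Alternatives fixed beforehand were the mean of per-cell values, a 10% detection filter, no filter with a pseudocount of 1 CPM, equal weights for the 17 clusters, scaling by a trimmed mean of M values, leaving out the fibroblast-like cluster 19, leaving out cells with under 1000 genes, and 3 other ways to rank cluster genes. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly behind mm10, in which 13945 of the 14421 symbols were found once. The scripts were tested on simulated libraries of 9480 genes, where 0% of genes set 1.5-fold apart and 100% of those set 3-fold apart came out over 2-fold, and 95.2% of the intervals held the true ratio. These libraries were drawn with counting error alone, which is what the intervals assume. That share checks the code and does not measure spread between cells or libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.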

Results

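Sca1pos held 6669 cells with 121167629 UMIs and Sca1neg 19754 cells with 158186154 UMIs. Sca1pos cells were deeper, with a median of 16981 UMIs and 3796 genes per cell against 7234 UMIs and 2367 genes. The median mitochondrial share was 3.01% and 2.84%. The series merged the sorted fractions to compare the Sca-1-positive epithelium, labelled as granuloma, with the Sca-1-negative epithelium of the same infected intestine.

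Interferon-response and antigen-presentation genes, genes associated with fetal or regenerating epithelium, and most goblet, Paneth and enteroendocrine genes stood higher in Sca1pos. Ly6a, which encodes the sorted protein, was at 258 CPM (interval 255 to 261) in Sca1pos and 2.12 (1.90 to 2.36) in Sca1neg, so the levels follow the sort. Lower in Sca1pos were Fbp1, an enzyme of gluconeogenesis, at 1.74 against 8.04 CPM, Adh1, an alcohol dehydrogenase, at 4.89 against 21.1, and several stem cell genes. Of 9480 genes compared, 202 were at least 2-fold higher and 35 at least 2-fold lower in Sca1pos. With the 17 clusters weighted equally these numbers were 132 and 22.

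Over all cells, the highest ratio after Ly6a was that of the annexin gene Anxa10, at 21.3 CPM against 0.348 (log2 ratio 5.93, interval 5.55 to 6.35). Alox15, a lipoxygenase, was at 5.42 against 0.107 (log2 ratio 5.66, 4.97 to 6.44), the secreted glycoprotein gene Lrg1 at 42.0 against 1.04 (5.33, 5.11 to 5.57) and Anxa1 at 9.95 against 0.278 (5.16, 4.73 to 5.63). Iigp1, an interferon-inducible GTPase, had a log2 ratio of 4.50, Usp18, which removes the interferon-induced modifier ISG15, one of 3.37, and the chemokine gene Cxcl9 one of 3.22. The adaptor gene Sh3kbp1 had 3.82, Khdc1a 3.60 and the fucosyltransferase gene Fut2 3.48. Chgb, a granule protein of endocrine cells, was at 384 against 40.2 CPM (3.25, 3.22 to 3.29). With the 17 clusters weighted equally the log2 ratios of Anxa10, Lrg1 and Anxa1 were 2.97, 3.88 and 3.47, those of Fut2, Usp18 and Chgb 2.06, 1.98 and 1.97, and those of Sh3kbp1 and Khdc1a 3.12 and 3.14. Alox15 had 5.13, Iigp1 4.84 and Cxcl9 3.86 on that scale, so Anxa10 was no longer next to Ly6a. Anxa10 and Lrg1 are leading genes of cluster 12, which came 94.8% from Sca1pos. Ly6a lies on chromosome 15 from 74994877 to 74998031, Anxa10 on chromosome 8 from 62057042 to 62123150, Lrg1 on chromosome 17 from 56119678 to 56122001 and Iigp1 on chromosome 18 from 60376027 to 60392634. All are protein-coding in the annotation.

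Among the lowest ratios, Fbp1 had a log2 ratio of -2.21 (-2.42 to -2.00) and Adh1 one of -2.11 (-2.24 to -1.98). Gkn3, a gene on the stem list, was at 8.58 against 24.5 CPM (-1.51, -1.61 to -1.41). Fgfbp1, which binds fibroblast growth factors, was at 22.0 against 58.3 (-1.41), and Lrat, which esterifies retinol, at 3.03 against 7.88 (-1.38). The immediate early gene Fosb had -1.37, the arginase gene Arg2 -1.36 and Rgcc -1.32. Adck3, Gstm2, the transporter gene Abcb1a and Slc16a12 had -1.53, -1.47, -1.32 and -1.31. Fbp1 lies on chromosome 13 from 62864753 to 62888282 and Adh1 on chromosome 3 from 138260991 to 138290698.

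**Figure D1:**
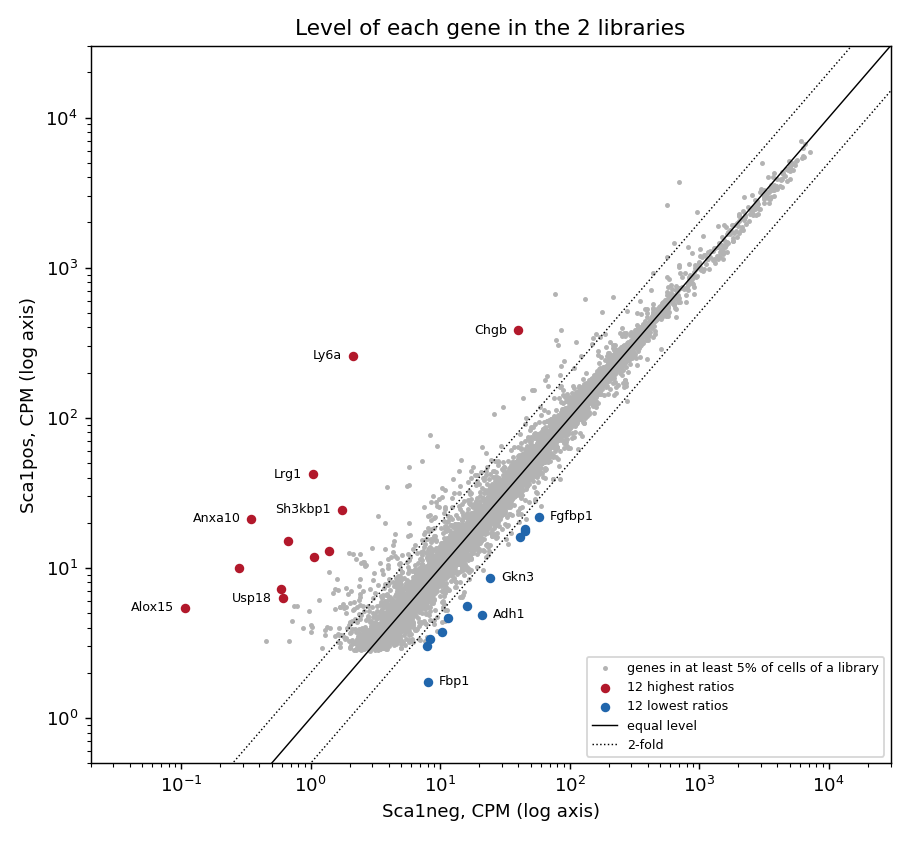
Each point is a gene, with its level in Sca1neg on the horizontal and in Sca1pos on the vertical axis, in CPM on log axes; red and blue points are the 12 highest and 12 lowest ratios and some are named. Ly6a stands at 258 against 2.12.

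Of the other sort genes, Epcam was at 1986 against 1944 CPM (log2 ratio 0.03) and Cd44 at 70.0 against 59.1 (0.24). Ly6a UMIs were found in 83.4% of Sca1pos and 1.25% of Sca1neg cells, and in 43.8% (42.6 to 45.015) and 0.508% (0.412 to 0.619) after thinning to 3000 UMIs. Lgr5, the marker of crypt base stem cells, was at 1.13 against 4.13 CPM and was found in 1.80% and 2.99% of cells, or 0.285% (0.172 to 0.445) and 1.16% (1.01 to 1.32) after thinning. In fibroblast-like cluster 19 it was found in 0 of 14 Sca1pos and 0 of 19 Sca1neg cells, with intervals up to 23.2% and 17.6%, too few cells for a background share. In enterocyte-like cluster 8, taken as a background after its values were seen, it was found in 0.471% (0.057 to 1.69) of 425 Sca1pos and 0.102% (0.00259 to 0.568) of 978 Sca1neg cells, with median depths of 14369 and 5821.5 UMIs. After thinning it was found in 0 cells of cluster 8, with intervals up to 0.864% and 0.380%, so the thinned share in Sca1pos is not shown to lie above background at this depth. Lgr5 was under the 5% filter.

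The interferon response list had a median log2 ratio of 1.53 over 24 members, 19 of them over 1.5-fold higher in Sca1pos and 0 lower. Of these members 12 passed the filter in Sca1pos alone, and the median over all 29 members above 0 in both libraries was 1.65. Its highest members were Iigp1 and Cxcl9, and its lowest Ifitm3 at 0.10 and Cxcl10 at 0.09. All 7 genes of the MHC class II list, whose products serve the presentation of peptides to CD4 T cells, were over 1.5-fold higher, with a median of 1.15. H2-DMb1 had 1.61 and H2-Aa 1.47, and Ciita, the class II transactivator, had 1.11 and Cd74 1.08. Among 9 compared genes of the MHC class I list the median was 0.59, with 5 over 1.5-fold higher, from Tap1 at 1.35 and H2-T23 at 1.11 to H2-Q2 at 0.31 and H2-T3 at -0.34. Of the immune cell lists, the 2 genes that passed the filter were Cd79b at -0.07 and Cd14 at 0.23. Under the filter, Jchain, a plasma cell gene, was at 31.0 against 5.88 CPM (log2 ratio 2.397), in 4.53% and 0.572% of cells, and Mzb1, Lyz2 and Cd79a had 2.72, 1.81 and 1.73. Without the filter the B cell and plasma cell median was 2.06 over 4 members and the myeloid median 0.63 over 5. C1qa, C1qb and Ccl5 were listed at 0 in Sca1neg and found in 0.360%, 0.135% and 0.165% of Sca1pos cells. Ptprc, which encodes CD45, was listed at 0 in Sca1pos and found in 0.076% of Sca1neg cells.

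The fetal-associated and regeneration list had a median of 1.76 over 7 members, 5 of them over 1.5-fold higher, with Anxa1 at 5.16 and S100a6 at 2.22 highest and Krt7 at 0.57 and Cldn4 at 0.25 lowest. All 11 compared goblet genes were over 1.5-fold higher, with a median of 1.29. Retnlb, a secreted effector against nematodes, was at 664 against 77.6 CPM (log2 ratio 3.10) and Zg16 had 2.06, while Fcgbp had 0.94 and Tff3 0.75. All 6 compared Paneth genes were over 1.5-fold higher (median 1.54), from Mmp7 at 3.20 and Itln1 at 2.16 to Defa17 at 1.27 and Defa24 at 0.74. Under the filter, at no more than 1.03 CPM in either library, Defa21, Defa22, Defa23 and Defa26 had -0.76, -1.86, -0.68 and -0.06. All 6 compared enteroendocrine genes were over 1.5-fold higher (median 2.36), with Chgb at 3.25, Chga at 3.15, Gip at 1.91 and Cck at 0.92, but 5 of the 6 passed the filter in Sca1pos alone. Under the filter, Ghrl was at 16.4 against 52.4 CPM (log2 ratio -1.68), and Gcg and Neurog3 had -1.10 and -0.67. Over all members above 0 in both libraries the enteroendocrine median was 1.21, with 12 of 15 above 0, and the Paneth median 1.27, with 7 of 11 above 0. The type 2 response list had a median of 1.41 over 11 members, led by Retnlb and Itln1 and with Gsdmc2 at 0.40 and Gsdmc4 at 0.04 lowest. With the 17 clusters weighted equally the goblet median was 0.14, the Paneth median 0.54, the enteroendocrine median 1.23 and the type 2 median 0.50. In cells of 8000 to 12000 UMIs they were 2.74, 2.69, 3.60 and 2.10. The 1.23 rests on the 6 compared genes, of which Cck had -0.38 with equal weights. With equal cluster weights and under the filter, Ghrl, Gcg, Neurog3, Pyy, Neurod1 and Pax6 had -2.98, -2.405, -1.94, -0.81, -0.43 and -0.175. Sst, Cpe and Tph1 had 0.19, 0.31 and 2.38. Over the 38 goblet, Paneth and enteroendocrine members above 0 in both libraries the median with equal weights was 0.146.

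The antimicrobial and oxidative defence list had a median of 0.43 over 10 members, 4 higher and 1 lower by over 1.5-fold. Reg3b and Reg3g, secreted lectins that act on bacteria, were at 3701 against 701 and 2618 against 564 CPM, with Pigr at -0.44 and Ccl20 at -0.69. The glycolysis and hypoxia list had 0.50 over 14 members, with Bnip3 at 1.46 and Eno1 at 1.08 highest and Ndrg1 at 0.17 and Pdk1 at 0.06 lowest. The stem list had -0.36 over 10 members, 4 of them over 1.5-fold lower, from Ascl2 at 0.07 and Rnf43 at 0.02 to Axin2 at -1.15 and Gkn3, and had -0.75 in cells of 8000 to 12000 UMIs and -0.62 over the 12 members above 0 in both libraries. The retinol and xenobiotic metabolism list had -0.38 over 9 members, 2 of them over 1.5-fold lower, and 0.07 in cells of 8000 to 12000 UMIs, with Gsta1 at 0.69 and Gsta4 at 0.39 highest and Ces2a at -1.30 and Adh1 lowest.

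Over all cells, medians of the other lists with at least 5 compared members were closer to 0. The Notch pathway list had -0.28, with Atoh1, which starts secretory differentiation, at 1.003 and Hes1 at -0.35. The immediate early and heat shock list had -0.20, from Hspb1 at 0.98 to Fosb at -1.37, but 0.015 with equal cluster weights and a median above 0 in 9 of 17 clusters. The p53 target and apoptosis list had 0.21, from Fas at 0.40 to Pmaip1 at -0.42. The lipid and sterol metabolism list had 0.12, with Scd1 at 1.43 and Hadh at -0.36, and the enterocyte list 0.01, with Apoa1 at 1.19 and Fabp2 at -0.83. The cycling list had 0.05, the replication list -0.03, the Wnt target list 0.07, the YAP target list -0.06, the quiescent or reserve stem cell list -0.05 and the epithelial list 0.12. In cells of 8000 to 12000 UMIs the cycling median was -0.77 and the enterocyte median 0.93. The cluster make-up of the libraries differs among those cells: enterocyte-like cluster 8 held 9.12% of them in Sca1pos and 2.68% in Sca1neg. With equal cluster weights the cycling median was 0.24 and the enterocyte median -0.06. Inside clusters the cycling median was above 0 in 14 of 17 and the enterocyte median in 2 of 17. Medians of the interferon, MHC class I, MHC class II, fetal-associated, goblet, Paneth, enteroendocrine, type 2, antimicrobial and glycolysis lists lay at percentile 100 of matched random lists, and those of the stem, retinol and immediate early lists at percentile 0. The Ly6 family list had 2 compared members, Ly6a and Ly6e at 1.58, with a median of 4.26. The tuft list had 2, Cd24a at -0.05 and Ptpn6 at -0.34, and the endothelial list had Esam at -0.02. The T cell and NK cell, mast cell and eosinophil, fibroblast and erythroid lists had 0 compared members.

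**Figure D2:**
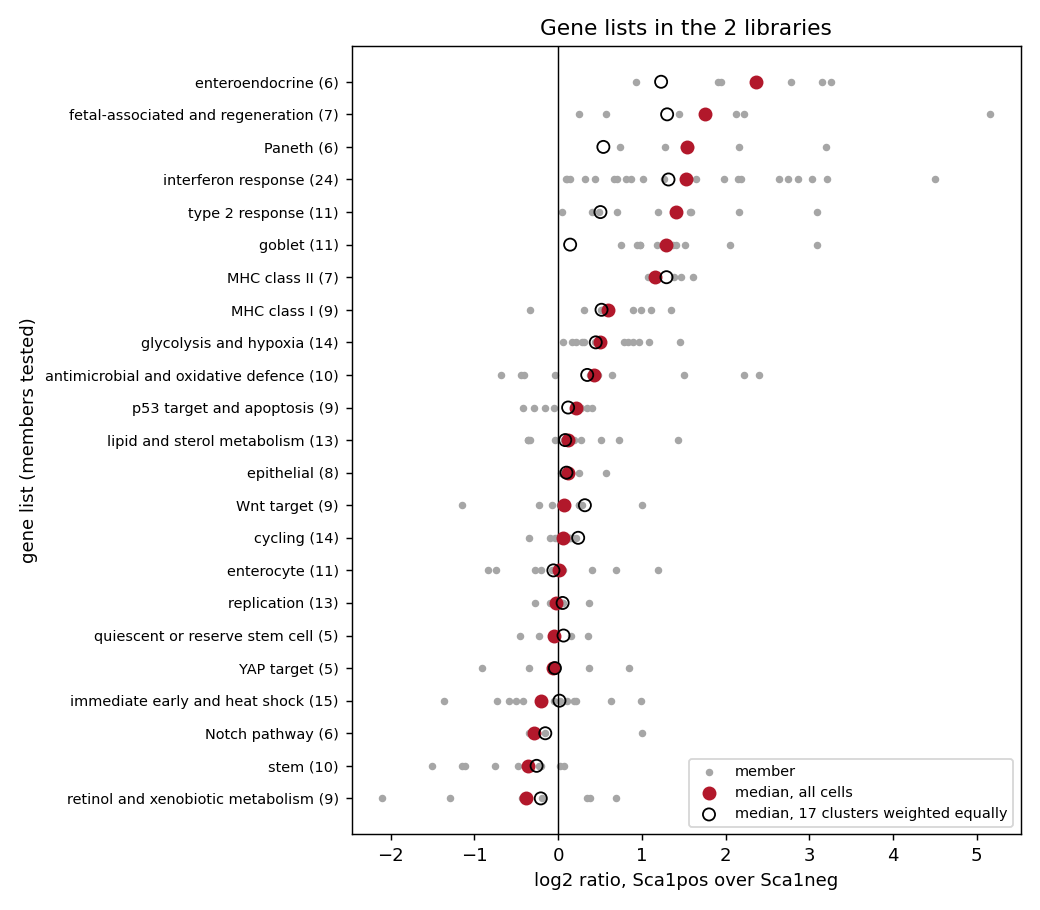
Each row is a list with at least 5 compared members; grey points are members, filled points the median over all cells and open points the median with the 17 clusters weighted equally, as log2 ratios of Sca1pos over Sca1neg. The interferon median is 1.53 and 1.32, and the goblet median 1.29 and 0.14.

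The authors' clusters describe which cell types the sort held. Cluster 1 was cycling-like, led by Nusap1, Aurka and Prc1, cluster 5 replication-like, led by Cdc6 and Cdt1, and cluster 6 stem-like, with Gkn3 and Olfm4 among its leading genes beside Rgcc, Edn1 and Aqp4. Cluster 8 was enterocyte-like, led by Apoa1, Mep1b, Il18, Fabp1 and Spink1, and cluster 10 goblet-like, led by Spdef, Atoh1 and Fcgbp. Cluster 15 was enteroendocrine-like, led by Isl1, Cck, Scg3, Ghrl and Chgb, cluster 17 tuft-like, with Lrmp and Rgs13 among its leading genes, and cluster 19, with 33 cells, fibroblast-like, led by Pdpn and Dcn. Cluster 11 held 3 goblet and 3 Paneth markers among its 10 leading genes, Zg16, Retnlb, Mmp7 and Ang4 among them, and stays unnamed. Also unnamed were clusters 0 and 9, led by the histone genes Hist1h1a and Hist1h1b, cluster 2, led by Ccl20, Hbegf, Areg and Atf3, cluster 3, led by Cxcl10 and Tnf, cluster 4, led by Rbp7, cluster 7, led by Car4 and Arg2, cluster 13, led by Creb3l3, cluster 14, led by Apol10a, cluster 16, led by Slc12a2, and cluster 18, with AY761184 and Mptx2 among its leading genes. Cluster 12 was led by Anxa10, Lrg1, Serpinb5, Reg3b and Reg3g and stays unnamed.

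The cell type lists stood apart in single clusters. The goblet median over the other clusters was 2.11 in cluster 10 and 5.39 in cluster 11, where the Paneth median was 4.43. The enterocyte median was 3.34 in cluster 8, the enteroendocrine median 9.84 in cluster 15, the tuft median 8.36 in cluster 17 and the fibroblast median 14.13 in cluster 19. The stem median was 1.53 in cluster 6, 1.10 in cluster 3 and 1.57 in cluster 18, where the Paneth median was 1.55. Of the cluster and list pairs with at least 5 compared members, 21 had a median of at least 1.

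Cluster 12 held 13.9% (13.1 to 14.8) of Sca1pos and 0.258% (0.192 to 0.339) of Sca1neg cells. It came 94.8% from 1 library, and its leading genes differed between the libraries inside it (median log2 ratio 1.08), so it may be that library and not a cell type. Tuft-like cluster 17 held 2 of 6669 Sca1pos and 291 of 19754 Sca1neg cells, or 0.030% (0.0036 to 0.108) and 1.47% (1.31 to 1.65). Cluster 11 held 7.84% (7.21 to 8.51) and 2.96% (2.73 to 3.20), cluster 9 held 9.78% and 3.37%, and replication-like cluster 5 held 11.9% and 6.98%. Cluster 2 held 2.83% of Sca1pos against 10.9% of Sca1neg cells, cluster 13 1.005% against 4.14% and cycling-like cluster 1 6.01% against 10.3%. Cluster 18, with the high stem median given above, held 0.150% (0.072 to 0.276) against 1.05% (0.915 to 1.21), or 10 and 208 cells. Cluster 3, also high in the stem list, held 4.53% against 10.0%. In clusters 18 and 3, 2 and 3 of the 10 leading genes were over 2-fold apart between the libraries. Shares of stem-like cluster 6, 2.94% and 7.42%, and enteroendocrine-like cluster 15, 3.55% and 1.48%, are not read as a difference, since 4 and 6 of their 10 leading genes were over 2-fold apart between the libraries. In all, 6 clusters were over 1.5-fold higher and 9 over 1.5-fold lower in share in Sca1pos, clusters 15 and 6 among them. The Sca-1 gate and the deeper Sca1pos cells can set these shares.

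**Figure D3:**
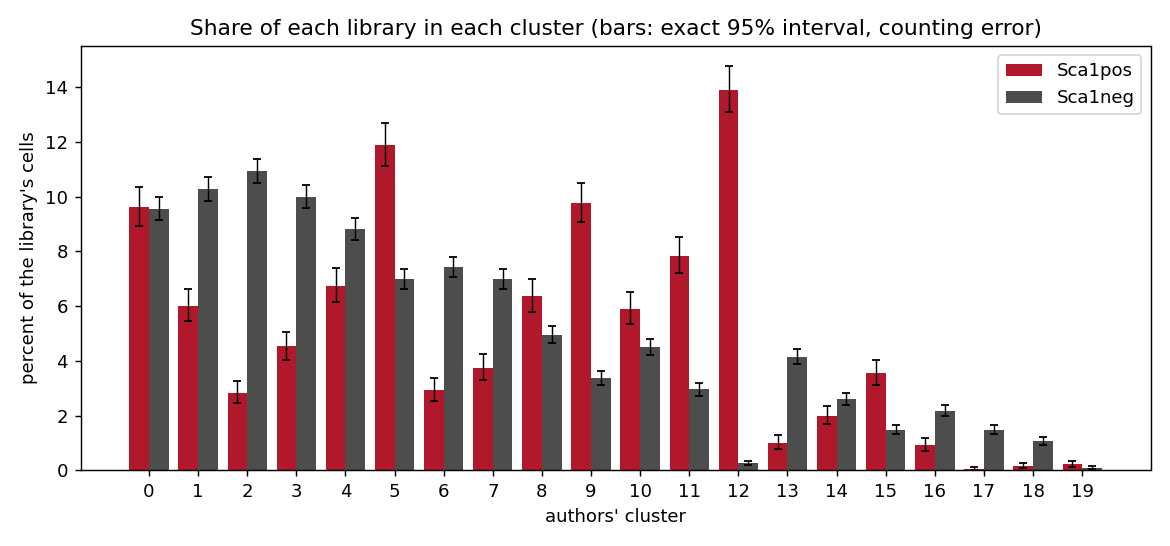
Bars give the percent of each library's cells in each authors' cluster, from 0, with exact 95% intervals for counting error. Cluster 12 holds 13.9% of Sca1pos and 0.258% of Sca1neg cells.

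Inside clusters, the interferon response median was above 0 in 17 of 17 clusters, from 0.43 in cluster 12 to 1.78 in cluster 3, and the MHC class II median in 17 of 17, from 0.65 in cluster 12 to 1.93 in cluster 16. The fetal-associated median was above 0 in 17 of 17, from 0.47 in cluster 16 to 2.31 in stem-like cluster 6. Ly6a was higher in Sca1pos in 17 of 17 clusters with an interval above 0, as were Lrg1, Sh3kbp1, Reg3b, Reg3g and Cd74. The stem median was above 0 in 1 of 17 clusters, cluster 12 at 0.06, and was lowest in cluster 14 at -1.01. Fgfbp1 was lower in 17 of 17 clusters, with an interval under 0 in 16, and Gkn3 was lower in 16. The goblet median was above 0 in 17 of 17 clusters, from 0.05 in cluster 11 to 1.06 in enteroendocrine-like cluster 15, with 0.28 in goblet-like cluster 10. The Paneth median was over 1.5-fold higher in 14 of 17 clusters and the median of the 6 compared enteroendocrine genes in 17 of 17, from 1.03 in cluster 7 to 2.03 in cluster 0. Of the compared genes, Defa24 went the other way, with a ratio below 1 in 15 of 17 clusters. Its interval lay under 0 in 11 and above 0 in 1, and its log2 ratio with equal cluster weights was -0.406. Tff3 had -0.405 on that scale, with a ratio below 1 in 7 clusters, an interval under 0 in 6 and above 0 in 2. Cck, Fcgbp and Spdef, also compared, had -0.384, -0.159 and -0.076 on that scale, with ratios below 1 in 1, 5 and 7 clusters. Of the genes under the filter, Ghrl was lower in Sca1pos in 17 of 17 clusters, with an interval under 0 in 12. Gcg had a ratio below 1 in 16 and Neurog3 in 12, each with an interval under 0 in 3.

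**Figure D4:**
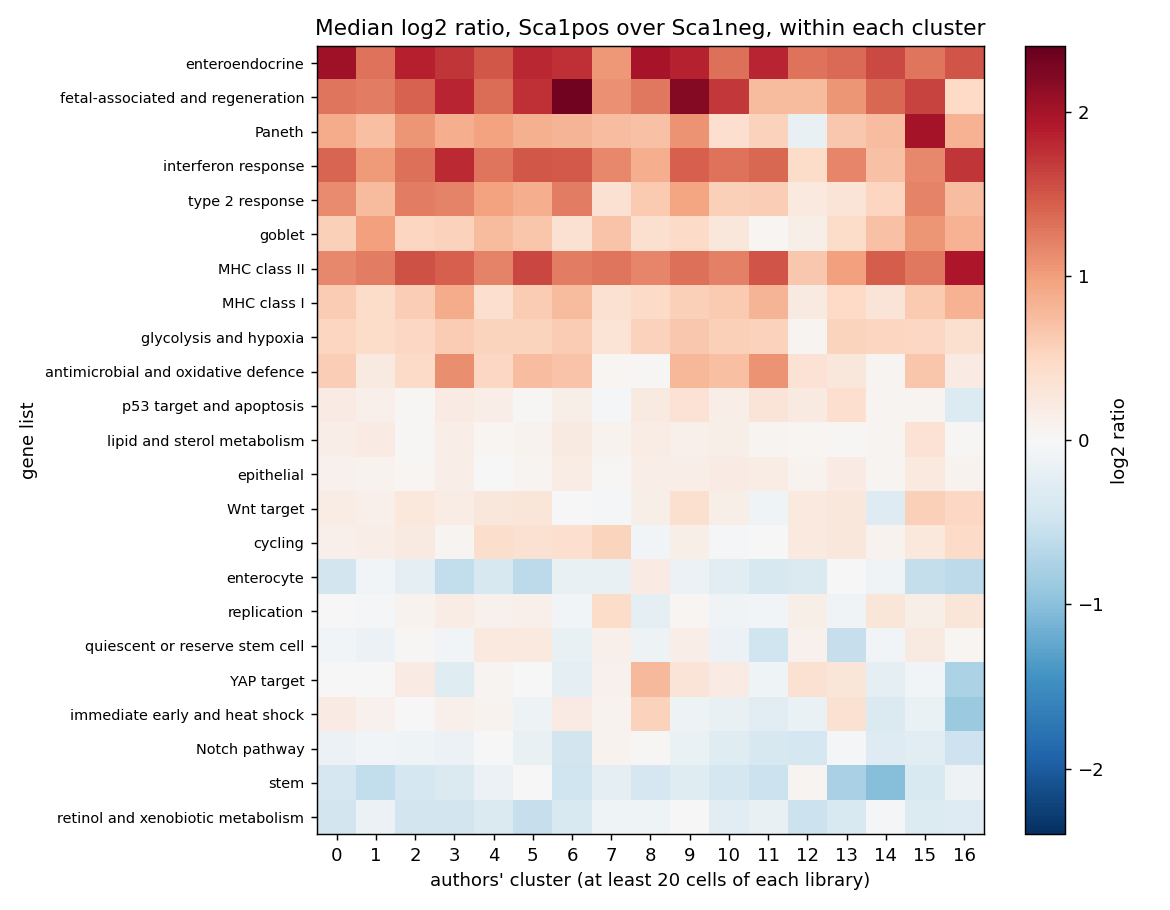
Colour gives the median log2 ratio of each list, Sca1pos over Sca1neg, inside each of the 17 clusters with at least 20 cells of each library. The interferon response row runs from 0.43 to 1.78.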

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

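The 2 tests of immune cells, that of separate preparation and the values over 38 secretory members were chosen after the results they measure were seen. The YAP target list, with 5 compared members, stood out because the same contrast went opposite ways in 2 clusters: its median log2 ratio of Sca1pos over Sca1neg was 0.782 in enterocyte-like cluster 8 and -0.759 in cluster 16. The split was not particular to this list. The immediate early and heat shock list, with 15 compared members, was also highest in cluster 8, at 0.549, and lowest in cluster 16, at -0.883. Neither difference was tested, and cluster 16 holds 61 Sca1pos cells.

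Most goblet, Paneth and enteroendocrine genes were higher in Sca1pos, with a median log2 ratio of 1.505 over the 23 members past the 5% filter and 1.259 over the 38 above 0 in both libraries, of which 7 were lower. Cells outside clusters 10, 11 and 15 carried 1.33% of the excess UMIs of the 23 and 1.26% of those of the 38. This argues against free RNA from secretory cells as the main source of that summed excess. The sum follows the most abundant genes, and lower genes can offset higher ones in it. It does not decide the ratios of single genes or those inside clusters. Chgb UMIs were found in 32.6% of Sca1pos cells, while enteroendocrine-like cluster 15 held 3.55% of these cells. Chgb was higher in 17 of 17 clusters with an interval above 0, while Ghrl was lower in 17 of 17. Free RNA may still add to the ratios inside clusters. With the 17 clusters weighted equally the median was 0.356 over the 23, between the bounds set for a cell mixture and for a difference inside clusters, and 0.146 over the 38, under the bound set for a cell mixture. With equal weights each gene's ratio is taken between its mean CPM over the clusters, so it follows the clusters where the gene is highest. It does not measure the typical difference inside clusters: the goblet median was 0.14 by it, yet above 0 in 17 of 17 clusters. A cell mixture and a difference inside clusters cannot be told apart, given this limit and since the filter moves the value across a bound. More secretory cells under the Sca-1 gate may account for part of the pattern.

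Interferon response and MHC class II genes were higher in Sca1pos, with a median of 1.38 over 31 members. A different cell mixture is argued against, as the median with equal cluster weights was 1.294. Inside clusters the median of these lists was above 0 in 17 of 17, with a lowest value of 0.504. Depth per cell is argued against too, as cells of 8000 to 12000 UMIs kept 87.73% of the median, though the cluster make-up differs there too. The gate removed CD45-positive cells, yet cells with a UMI of a tested immune gene held 42.04% of the Cd74 UMIs of Sca1pos. However, 33.8% of all Sca1pos cells had such a UMI and these genes were only Cd79b and Cd14, so that value decides nothing. Without cells holding a UMI of any of 16 immune list genes, Cd74 kept 95.09% of its log2 ratio. That left 3899 of 6669 Sca1pos and 15796 of 19754 Sca1neg cells, and the value covers Cd74 alone among the 31 members. Separate sorting and library preparation cannot be told apart from the groups, with 1 library per sort. A response of the epithelium labelled as granuloma may also account for the pattern and was not tested. The label and the Sca-1 gate name the same fraction, so such a response cannot be told apart from selection by the gate.

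Reg3b and Reg3g UMIs were found in 98.5% and 98.8% of Sca1pos cells, and in 80.5% and 87.1% after thinning to 3000 UMIs. In the fibroblast-like cluster 19 their summed level in 14 Sca1pos cells was 39.37% of the median of the epithelial clusters, between the bounds set for free RNA and against it, so part of the share may be free RNA. Free RNA does not account for the difference between the 17 epithelial clusters with at least 20 Sca1pos cells, where the highest level was 10.14 times the lowest; tuft-like cluster 17, with 2 Sca1pos cells, lay lower still at 435 CPM (225 to 760). Whether cells of the lowest clusters express either gene stays open.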

How the results depend on the processing

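The filter of 5 CPM, the depth window, the runs without cluster 12 those without the highest doublet scores and the lists without a filter were chosen after seeing the data. Genes at least 2-fold higher in Sca1pos, 202 as reported, numbered 132 with the 17 clusters weighted equally, of which 122 were among the 202, and 354 in cells of 8000 to 12000 UMIs. Genes at least 2-fold lower, 35 as reported, numbered 19 with a 10% filter, which compares fewer genes, 22 with equal cluster weights, 65 with no filter, 54 at 5 CPM and 91 in the depth window. The depth window holds shallow Sca1pos and deep Sca1neg cells, 899 and 5303, with another cluster make-up: cluster 11 held 17.8% and 0.849% of them, against 7.84% and 2.96% of all cells. Apart from the filters the cause was not tested. Lists over 1.5-fold higher numbered 8 as reported and 4 with equal cluster weights, where the goblet, Paneth, type 2 and MHC class I medians were under that size. The enteroendocrine list, at 1.23, is 1 of these 4 only on its 6 compared members. Of those, 5 passed the filter in Sca1pos alone, and members under the filter went both ways with equal cluster weights. In the depth window 11 lists were higher and 2 lower, against 0 lower as reported, and 14 of 23 medians moved by at least 0.2. Over all members above 0 in both libraries 9 of 26 lists were higher and 1, the stem list, lower; the added higher list was the myeloid one. Of the 27 named ratios, 23 moved beyond their interval with equal cluster weights and 20 in the depth window, and 0 turned direction among those at least 2-fold apart. Of the 100 leading cluster genes, 17 were kept when ranked by means on the log scale and 60 with a 10% filter; the cause was not tested. Numbers of clusters over 1.5-fold apart in share stayed at 6 and 9 in all 3 alternatives run. No paired analysis was possible because each group holds 1 library. The alternatives for cells with and without Ly6a UMIs were not run, since the libraries could be told apart. The 5% filter is reached more easily by the deeper Sca1pos cells.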

Other observations

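Retnlb UMIs were found in 19.3% (18.4 to 20.3) of Sca1pos and 4.59% (4.29 to 4.89) of Sca1neg cells after thinning to 3000 UMIs, and in 48.9% and 7.53% before. In fibroblast-like cluster 19, 3 of 14 thinned Sca1pos cells had one, 21.4% (4.66 to 50.8), with median depths of 16981 and 6702 UMIs. With 14 cells the background share is not known well enough to say whether the share over all Sca1pos cells lies above it. Ly6a UMIs were found in 12 of 19 Sca1neg cells of cluster 19, at 665 CPM, against 2.12 over the whole Sca1neg library. Anxa1 was at 225 CPM in the same cells and at 0.278 over the whole library.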
